A study of Homo sapiens with 14 samples.

How the data were processed

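Gene expression was measured in 14 samples of U2OS, a human osteosarcoma cell line, that stably expressed ER-E2F1, a fusion of the transcription factor E2F1 to an estrogen receptor domain that is activated by 4-hydroxytamoxifen (OHT). Per the labels' protocols, cells were infected with a lentivirus carrying a scrambled hairpin or with 1 of 2 hairpin viruses, shFOXO33 and shFOXO707, each directed against both FOXO1 and FOXO3. The medium was changed to serum-free medium 24 h after infection for 24 h, and the cells were then kept with or without 20 nM OHT for 6 h. Each sample was 1 Affymetrix array, and the groups were taken from the sample titles. Scrambled cells without and with OHT had 4 arrays each, each hairpin had 1 array without OHT and 2 arrays with OHT, and the hairpins were also pooled into 2 arrays without OHT and 4 arrays with OHT. Replicate numbers that the titles did not give were assigned in accession order and only name an array. The sources used here do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

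The authors deposited 1 value per probe set and array as a linear intensity, and the signals were made with MAS5, per the submitters' processing notes; the MAS5 version is not given in the sources used here. The mean of each array after leaving out the lowest and highest 2% of probe sets was 500 to the nearest whole unit on all 14 arrays, so the deposited intensities were treated as scaled to a common trimmed mean. No background, detection call or probe-level value was used here. Array signals have no sequencing depth, and the number of arrays limits the precision.

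The table held 22277 probe sets, of which 62 were array controls. The probe annotation paired 19064 of the others with 1 gene, 1043 with several genes and 2108 with none, and symbols were updated through the Entrez identifier for 19052 of them with a RefSeq gene table of assembly GRCh38.p14, from which no coordinates were taken. Probe sets that named several genes or none were left out of the comparisons. Signals were transformed as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. Probe sets were kept when their mean log2 value over the 14 arrays lay above the 40th percentile of probe sets naming 1 gene, a level of 6.57 or a signal of 79.1, which left 11438. Each gene was represented by its probe set with the highest mean, giving 7720 genes.

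Differences were tested with limma version 3.58.1 in R version 4.3.3 (lmFit, then eBayes with a trend in the variance prior) over all 14 arrays in 4 groups. The hairpins were pooled, so that the spread between them entered the error. It counted only in part, because it was averaged with the smaller spread between arrays of the same virus. Arrays of the same hairpin also counted as separate replicates, so knockdown calls can be too many. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 7720 genes, and all tests were two-sided. The contrasts were OHT against no OHT in scrambled cells and in knockdown cells, knockdown against scrambled with and without OHT, and the interaction, which is the response to OHT in knockdown cells minus that in scrambled cells. The difference between the hairpins with OHT was tested in a fit with 6 groups, as were the effects of each hairpin against scrambled cells. The probe sets of FOXO1, FOXO3, FOXO4 and E2F1 were tested in a separate fit of all 22215 probe sets that were not controls.

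There were 21 gene lists, 4 of them markers of cell types. They covered E2F cell cycle and DNA replication targets, mitosis and G2/M, apoptosis genes described as E2F1 targets, p53 targets, FOXO targets, the interferon response, immediate early and serum response genes, the unfolded protein and integrated stress response, cholesterol synthesis, glycolysis and hypoxia, autophagy, PI3K and growth factor signalling, replication-dependent histones, the extracellular matrix, estrogen receptor targets, inflammatory cytokines and NF-kB, ribosomal proteins, and epithelial, blood cell, neural and osteoblast markers. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 20 lists that had a measured member, and again with an estimated correlation and on ranks. For each list the calls were also counted with p-values adjusted over the list alone. The sign of a list's median and the direction of its test differed for 7 lists with OHT in scrambled cells, 6 with OHT in knockdown cells, 3 in each knockdown comparison and 4 in the interaction, and 0 of these lists were called.

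Genes named in the text were those with the 10 largest changes each way in each of the 4 contrasts between groups, among called genes whose arrays did not overlap between the groups. Added to these were the 5 largest each way in the interaction and in the hairpin difference, up to 4 members of each list with the smallest adjusted p in each contrast, and BCL2L11, TP73, PMAIP1, BBC3, CCNE1, CDC6 and CDKN1B where measured. All probe sets of FOXO1, FOXO3, FOXO4, FOXO6 and E2F1 that name only that gene were examined; FOXO6 had no probe set on the list of named probes. The groups, tests, filter, gene lists, naming rule and alternative settings were chosen before the data were examined, except 1 alternative that was added later and is named as such.

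The retained response was measured on 200 genes. These had the largest moderated t of limma for a rise with OHT in 2 of the scrambled arrays of each treatment. They were evaluated in the other 2 scrambled arrays of each treatment and in the knockdown arrays, over all 36 choices. Because comparisons against the same scrambled arrays share their chance values, the correlations and overlaps between them were also computed for 100 simulations of unchanged groups, for independent lists of the same sizes, and with the scrambled arrays split so that each comparison had 2 of its own.

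The alternatives were other pseudocounts (1 and 64), no filter and a filter at the 60th percentile, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, leaving out probe sets whose name ends in _x_at, 6 groups, only the arrays compared, each hairpin alone, no trend in the variance prior, a minimum change of 1 log2, a block for the replicate number, and leaving out each array in turn. The tests were tested on simulated data made from the measured means and spreads of the 7720 genes, with 200 genes changed, in 10 draws per comparison. Changes of 1 log2 were recovered in 92.8% of genes on average for OHT in scrambled cells, 90.4% for knockdown with OHT, 82.8% for knockdown without OHT, 83.2% for OHT in knockdown cells and 67.5% for the interaction. Changes of 0.5 log2 were recovered in 56.9%, 55.7%, 42.9%, 41.4% and 23.0% in the same order. False calls made up between 4.77% and 5.56% of calls on average, with up to 10.6% in 1 draw. The simulated arrays had independent noise with 1 spread per gene and no difference between the hairpins. These rates therefore do not cover genes in which the hairpins differ, in the knockdown and interaction comparisons. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15.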

Results

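Array signals were compared between U2OS osteosarcoma cells with and without activation of ER-E2F1 by OHT, and with and without hairpins against the forkhead transcription factors FOXO1 and FOXO3. The question was how transcription responds to E2F1 and which part of that response depends on FOXO1 and FOXO3. The 14 arrays comprised 4 scrambled arrays without OHT, 4 scrambled arrays with OHT, 1 array of each hairpin without OHT and 2 arrays of each hairpin with OHT. The median signal was 139 ± 2.49 (SD, n = 6) on arrays without OHT and 117 ± 1.85 (SD, n = 8) on arrays with OHT. Across the 7720 genes, which are not independent replicates, log2 values correlated at r from 0.992 to 0.994 for the 14 pairs of arrays of 1 group, from 0.956 to 0.958 for the 5 pairs of different hairpins with the same treatment and from 0.830 to 0.973 for the other 72 pairs. No pair of arrays shared identical values. The 3'/5' signal ratio of the ACTB control, a sign of RNA integrity, was 2.0 ± 0.06 (SD, n = 2) in shFOXO707 cells with OHT, against 1.61 ± 0.02 (SD, n = 2) in shFOXO33 cells with OHT and 1.65 ± 0.06 (SD, n = 4) in scrambled cells with OHT. The corresponding GAPDH ratio lay between 0.983 and 1.11 on the 14 arrays.

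The targeted genes were lower in cells with the hairpins, and both were higher after OHT. FOXO1 had a signal of 501 ± 32.7 (SD, n = 4) in scrambled cells with OHT and of 199 ± 48.5 (SD, n = 4) in knockdown cells with OHT. Its signals without OHT were 103 ± 8.45 (SD, n = 4) and 44.2 ± 7.13 (SD, n = 2). FOXO3 had signals of 1793 ± 45.2 (SD, n = 4) and 558 ± 293 (SD, n = 4) with OHT. Without OHT these were 449 ± 42.7 (SD, n = 4) and 206 ± 96.1 (SD, n = 2). In the fit of all probe sets the knockdown changed FOXO1 by -1.29 log2 with OHT (adjusted p = 8.85e-05) and by -0.99 without (adjusted p = 0.00838). FOXO3 changed by -1.81 with OHT (adjusted p = 0.00136) and by -1.13 without (adjusted p = 0.122), which was not called. Of the 3 probe sets that name both FOXO3 and FOXO3B, added after their values were seen, 2 changed by -1.75 and -1.78 with OHT (adjusted p = 0.000753 and 0.000448) and by -1.11 and -1.41 without (adjusted p = 0.0843 and 0.0216), and the other was below the filter. FOXO3 was left at 17.1% of the scrambled signal by shFOXO33 and at 45.1% by shFOXO707 with OHT, while FOXO1 was left at 32.4% and 47.1%. Without OHT, the single array of shFOXO33 held 30.7% of the scrambled FOXO3 signal and that of shFOXO707 held 60.9%. OHT raised FOXO1 by 2.12 ± 0.15 (SE) and FOXO3 by 1.96 ± 0.29 (SE) log2 in scrambled cells. The other FOXO1 probe set, with the lower mean, changed by -1.69 with knockdown and OHT and by -0.87 without OHT (adjusted p = 0.110). FOXO4, below the filter, fell by 0.79 with OHT (adjusted p = 0.0140) and differed by -0.26 with knockdown and OHT (adjusted p = 0.579). The 2 probe sets of E2F1 differed by -0.20 (adjusted p = 0.144) and 0.18 (adjusted p = 0.322) with OHT, and whether they detect the ER-E2F1 transcript is not given in the sources used here.

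**Figure D1:**
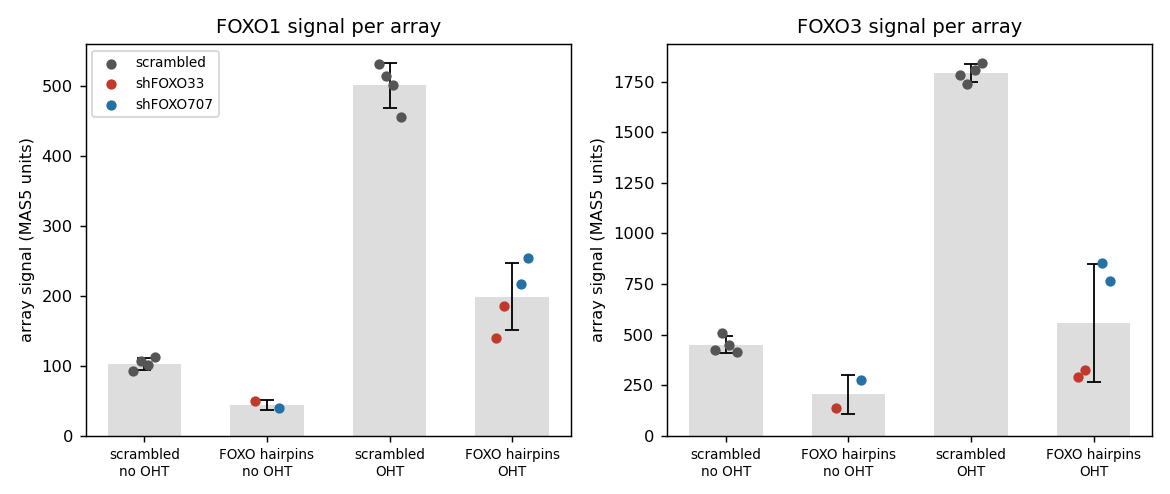
Signal (MAS5 units) of FOXO1 (the probe set with the higher mean) and FOXO3 on each array, with dots coloured by virus, bars at the group mean and error bars of 1 SD (n = 4, 2, 4 and 4 from left to right). Scrambled cells with OHT had a mean FOXO3 signal of 1793, and knockdown cells with OHT had a mean of 558, with the shFOXO33 arrays below the shFOXO707 arrays.

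Most of the measured genes changed with OHT in scrambled cells. No sample received OHT without carrying ER-E2F1, so effects of OHT itself are not separated from those of E2F1. Indirect changes over the 6 h are not separated either. HEY1, a transcriptional repressor that acts downstream of Notch, rose by 5.93 ± 0.07 (SE) log2, from a signal of 157 ± 16.6 (SD, n = 4) to 10472 ± 276 (SD, n = 4), and its adjusted p was 8.90e-16. The next largest increases were those of FA2H (4.73), a fatty acid hydroxylase, ABCG2 (4.65), a drug efflux transporter, and ID4 (4.65), an inhibitor of helix-loop-helix transcription factors. They were followed by TM6SF1 (4.44), the transcription factor MYB (4.38), KLHL21 (4.35), an adaptor of a ubiquitin ligase, the coactivator CITED1 (4.29), the hyaluronan-binding protein CEMIP (4.11) and GABBR2 (4.00), a subunit of the GABA-B receptor. ANKRD1 changed by -4.63 ± 0.12 (SE), from a signal of 1595 to 49.4, and CCN2, a secreted matricellular protein, by -3.62. Other large decreases were RIN2 (-4.05), the chemokine scavenger receptor ACKR3 (-3.98), ARID5B (-3.79), SOX9 (-3.67), a regulator of chondrocyte differentiation, TNFRSF11B (-3.63), which encodes osteoprotegerin, endothelin-1 gene EDN1 (-3.49), the sialyltransferase ST6GALNAC5 (-3.43) and MN1 (-3.32). In all, limma called 1854 genes higher and 3585 genes lower, of which 781 and 976 changed at least 2-fold. An unadjusted p under 0.05 was reached by 5603 genes. The median of all genes was -0.23 log2. When each array was centred on its own median 2494 genes were called higher and 2366 lower, so that the higher share moved from 34.1% to 51.3%, and after quantile normalization 2119 were higher and 3099 lower (40.6%).

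Among 57 measured E2F cell cycle and DNA replication targets, 21 rose and 16 fell, and after median centring 27 rose and 9 fell. The list was not called (adjusted p = 0.0592, and 0.632 with an estimated correlation). The cyclin E genes CCNE1 (2.61) and CCNE2 (2.91), SLBP (2.22), which binds histone mRNA, and DSCC1 (1.84), which acts in sister chromatid cohesion, rose, whereas the replication licensing factor CDC6 differed by 0.29 (adjusted p = 0.072). Of 34 mitosis and G2/M genes 4 rose and 25 fell, among them the kinetochore motor CENPE (-1.89), the ubiquitin-conjugating enzyme UBE2C (-1.25), TOP2A (-0.82) and the centromeric histone CENPA (-1.64). After median centring 5 rose and 22 fell. This list was called lower (adjusted p = 0.0264, but adjusted p = 0.632 with an estimated correlation), and leaving out probe sets whose name ends in _x_at gave an adjusted p of 0.0678. Of 20 apoptosis genes described as E2F1 targets 10 rose and 8 fell. The BH3-only gene HRK (2.88), the kinase gene MAP3K5 (3.56), PPP1R13B (1.68) and the BH3-only gene BCL2L11 (0.84) rose, and the initiator caspase gene CASP8 (-2.36) and PMAIP1 (-1.50) fell, while TP73 and BBC3 lay below the filter. Of 20 p53 targets 3 rose and 14 fell, including the repair gene XPC (-2.11), the death receptor FAS (-1.58) and TIGAR (-1.01). Of 25 FOXO targets 7 rose and 12 fell: the cell cycle inhibitor CDKN1B (1.46) and the pseudokinase TRIB1 (1.89) rose, and the transcription factors KLF6 (-3.18) and BCL6 (-2.35) fell. Adjusted p-values of these last 3 lists were 0.338, 0.213 and 0.874.

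The remaining lists were not called with OHT in scrambled cells, with adjusted p between 0.338 and 0.895, but most held genes that changed. Of 11 interferon response genes 2 rose and 6 fell, with USP18 at 3.03 and RIGI, a sensor of viral RNA, at -1.62. Of 19 immediate early and serum response genes 9 rose and 9 fell, for example KLF10 (1.95) and IER3 (-1.71). Of 18 unfolded protein and integrated stress response genes 5 rose and 7 fell (CHAC1 2.35, HERPUD1 -1.78). Of 16 cholesterol synthesis genes 3 rose and 10 fell (SC5D -0.98, MSMO1 -1.07), or 3 and 5 after median centring. Glycolysis and hypoxia genes went 8 up and 7 down of 21 (KDM3A 1.41, the glucose transporter SLC2A1 -1.83), or 12 up and 3 down after median centring. Autophagy genes went 3 up and 10 down of 20 (TFEB 1.95, ATG14 -1.20). Of 18 PI3K and growth factor signalling genes 7 rose and 9 fell, and the phosphatase PHLPP1 (2.65), RRAGD (2.50) and the kinase AKT1 (1.36) were among those that rose. Replication-dependent histones went 0 up and 5 down of 7 (H2BC5 -0.83), or 0 up and 2 down after median centring. Of 22 extracellular matrix genes 0 rose and 8 fell (TIMP3 -1.59), which turned to 7 up and 3 down after median centring but was 3 and 8 after quantile normalization. Of 21 ribosomal protein genes 0 rose and 13 fell (RPL18 -0.29), which turned to 6 up and 0 down after median centring but was 4 and 10 after quantile normalization. Estrogen receptor targets went 3 up and 2 down of 7 (MYB 4.38, the retinoic acid receptor RARA -2.07). Inflammatory and NF-kB genes went 3 up and 2 down of 7 (NFKB1 0.99, LIF -2.98). Among cell type markers, 1 of 4 epithelial genes rose and 1 fell (EPCAM 0.59, KRT18 -0.57), as did 1 and 1 of 3 neural genes (NEFL 0.69, OLIG2 -0.41). KRT18 lost its call without any 1 of 8 arrays (adjusted p up to 0.0879) and OLIG2 without any 1 of 3 (up to 0.0936), and after median centring their adjusted p was 0.225 and 0.306. KRT18 also lost its call without a filter (adjusted p = 0.0578) and without a trend in the variance prior (0.0531), OLIG2 after quantile normalization (0.220), and RPL18 after median centring (0.381) and when probe sets were averaged (0.150). Of 4 osteoblast genes 1 rose and 1 fell (MSX2 2.03, COL1A1 -0.44, with 1 of its 2 other probe sets at 0.01), and 0 of 12 blood cell markers were measured above the filter. After median centring the counts were 11 and 6 for apoptosis, 5 and 14 for p53, 8 and 10 for FOXO, 3 and 5 for interferon, 10 and 9 for immediate early, 5 and 6 for stress response, 5 and 9 for autophagy, 8 and 8 for PI3K signalling and 4 and 2 for NF-kB genes, and 1 and 0 for epithelial and for neural markers. Adjusted over the list alone, the counts of all 20 lists were as given, except 7 extracellular matrix genes lower and 0 epithelial genes lower.

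**Figure D2:**
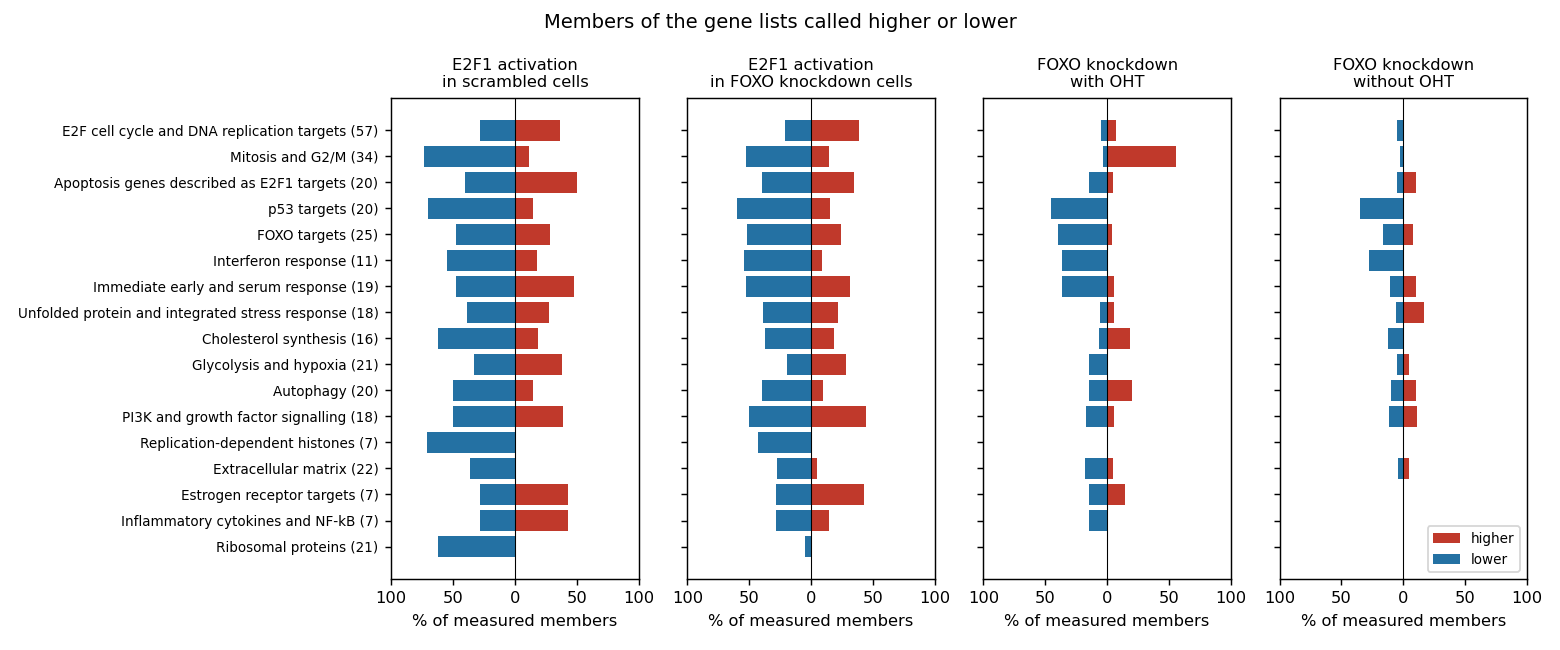
Percent of the measured members of 17 gene lists (number measured in brackets) called higher (red, right) or lower (blue, left) in each of the 4 comparisons between groups. With OHT in scrambled cells 25 of 34 mitosis and G2/M genes were lower (22 after median centring), and with knockdown and OHT 19 of them were higher (16 after median centring); 0 of 21 ribosomal protein genes were higher and 13 lower with OHT in scrambled cells, which turned to 6 higher and 0 lower after median centring and to 4 and 10 after quantile normalization.

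With OHT present, 1138 genes were higher and 618 lower in knockdown than in scrambled cells, of which 40 and 38 changed by 2-fold or more. This comparison does not separate loss of FOXO1 and FOXO3 from other differences between the viruses. After median centring 906 were higher and 730 lower, so that the higher share moved from 64.8% to 55.4%, and after quantile normalization 1043 were higher and 599 lower (63.5%). DYNLRB1, a dynein light chain, rose by 3.33 ± 0.10 (SE) log2, from a signal of 152 in scrambled cells to 1683 in knockdown cells, and HSD17B10, a mitochondrial dehydrogenase, rose by 3.03 ± 0.14 (SE), from 172 to 1533. The tumour suppressor NF2 (2.49), the mitochondrial serine carrier SFXN3 (2.27) and the homeobox gene PBX2 (1.89) followed. Next came TAPBP (1.66), which encodes tapasin, WDR77 (1.58), HMGA2 (1.56), CREB3L2 (1.54) and BLCAP (1.48). The largest decreases were those of the cyclin D2 gene CCND2 (-1.92), AHNAK2 (-1.84), FOXO3 itself (-1.81), PREPL (-1.81), and the RNA-binding protein gene RBMS2 (-1.76). The interferon-induced IFI6 fell by 1.67 ± 0.08 (SE), from a signal of 1098 to 332. Further decreases were those of CEMIP (-1.48), the ubiquitin-like ISG15 (-1.47), the lipid kinase gene PIP4K2C (-1.38) and EGR4 (-1.33). The hairpins differed in size for some of them: CCND2 changed by -0.80 with shFOXO33 and by -3.05 with shFOXO707, RBMS2 by -0.98 and -2.54, PIP4K2C by -1.96 and -0.80, and HMGA2 by 2.37 and 0.74. The cell cycle regulators CCNE1 (-0.08), CDC6 (0.02) and CDKN1B (-0.16) and the BH3-only gene PMAIP1 (-0.21) were not called. With only shFOXO33 arrays the counts were 2151 higher and 1670 lower, and with only shFOXO707 arrays 1875 and 1321, where both the effect and its error are those of 1 hairpin. With 6 groups, which changed the error alone, they were 2039 and 1601. The pooled error holds the spread between the hairpins only in part, so a call does not show that an effect exceeds that spread. With only the arrays with OHT numbered 1 and 2 the counts were 92 and 48, in a fit that also has fewer arrays.

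Of the 34 mitosis and G2/M genes, 19 were higher and 1 was lower with knockdown and OHT, and 25 and 1 when adjusted over the list alone. UBE2C rose by 0.58, CENPE by 0.72, the checkpoint kinase gene BUB1B by 0.56 and cyclin B2 gene CCNB2 by 0.41. The list was called higher (adjusted p = 3.51e-07), a call that was lost at adjusted p = 0.149 with an estimated correlation. A further 4 lists were called lower under both correlations. These were FOXO targets (1 higher and 10 lower of 25, or 1 and 12 over the list alone and 1 and 11 after median centring) and p53 targets (0 and 9 of 20, the same over the list alone). They also included interferon response genes (0 and 4 of 11, or 0 and 5) and immediate early and serum response genes (1 and 7 of 19, or 2 and 11). Their adjusted p-values were 0.000114, 0.000114, 0.000482 and 0.000482, and 0.0271, 0.0439, 0.0439 and 0.0439 with an estimated correlation. Among FOXO targets KLF9 (-0.73), KLHL24 (-0.60) and the PI3K inhibitor PIK3IP1 (-1.17) fell and the autophagy gene ATG14 (0.53) rose. Among p53 targets PHLDA3 (-0.63), the death receptors TNFRSF10B (-0.55) and FAS (-0.42) and the cell cycle inhibitor CDKN1A (-0.29) fell. Interferon response genes IFI44 (-1.17) and TRIM22 (-0.47) fell together with IFI6 and ISG15, and the immediate early genes NR4A1 (-0.64), EGR1 (-0.52), the phosphatase DUSP1 (-0.50) and PHLDA1 (-0.42) fell. PHLDA1 lost its call when all probe sets of a gene were averaged (adjusted p = 0.104), and after median centring 0 immediate early genes were higher and 7 lower. The ACTB 3'/5' ratio given for shFOXO707 with OHT, 2.0, lay above that of every other group, and the epithelial markers KRT8 (-0.50) and EPCAM (0.44) changed in opposite directions with this knockdown. EPCAM lost its call without replicate 1 of scrambled cells with OHT (adjusted p = 0.0501) and with only shFOXO33 (0.0522).

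Ribosomal protein genes had 0 members called in either direction, yet the list was called higher (adjusted p = 0.0223, but adjusted p = 0.696 with an estimated correlation). It lost that call after median centring (adjusted p = 0.114), without a trend in the variance prior (0.124) and with only shFOXO707 (0.936). Its median relative to that of all genes, 0.06 log2, turned to -0.01 after quantile normalization (adjusted p = 0.599) and to -0.02 with only shFOXO707. It also lost the call without replicate 2 of scrambled cells with OHT (adjusted p = 0.10) and without replicate 1 (0.252) or 2 (0.0910) of shFOXO33 with OHT. E2F targets had 4 higher and 3 lower (BLM 0.44, ASF1B -0.50), which turned to 2 and 3 after median centring, and apoptosis genes 1 higher and 3 lower (CASP8 0.85, BCL2L11 -0.38). The cystine transporter SLC7A11 rose by 1.34 among stress response genes (1 higher, 1 lower). HMGCS1 fell by 0.97 among cholesterol synthesis genes (3 higher, 1 lower), but its other probe set was at 0.21, and its call was lost when probe sets were averaged (adjusted p = 0.163). Of glycolysis and hypoxia genes 3 fell and 0 rose (HK2 -0.58). Autophagy genes went 4 up and 3 down (MAP1LC3B -1.10), PI3K signalling genes 1 and 3 (IGF1R -0.79), and extracellular matrix genes 1 and 4 (TNC 0.73, COL6A1 -0.36). The counts were for estrogen receptor targets 1 and 1 (cyclin D1 gene CCND1 -1.02), NF-kB genes 0 and 1 (TNFAIP2 -0.68), epithelial markers 1 and 1, osteoblast markers 0 and 1 (MSX2 -0.57), and histones and neural markers 0 and 0. After median centring cholesterol synthesis genes turned to 2 higher and 3 lower, autophagy genes to 2 and 4, glycolysis and hypoxia genes to 0 and 4 and estrogen receptor targets to 0 and 1. After quantile normalization E2F targets had 3 and 2, cholesterol synthesis genes 2 and 1 and autophagy genes 3 and 3. Adjusted p-values of these lists lay between 0.119 and 0.917, and the counts adjusted over the list alone differed for E2F targets (3 and 2), apoptosis (1 and 2), cholesterol synthesis (4 and 2) and autophagy (5 and 4).

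Without OHT, 374 genes were higher and 229 lower in knockdown than in scrambled cells, 29 and 21 of them at least 2-fold. After median centring 300 were higher and 278 lower, so that the higher share moved from 62.0% to 51.9%, and after quantile normalization 430 were higher and 282 lower (60.4%). HSD17B10 (2.09 ± 0.17, SE), DYNLRB1 (2.01 ± 0.13, SE), the secreted protease ADAMTS1 (1.96 ± 0.19, SE) and TAPBP (1.92) rose most. They were followed by NF2 (1.80), the actin-bundling FSCN1 (1.60), SFXN3 (1.59), TRIM58 (1.21), CPOX (1.16), an enzyme of heme synthesis, and PIP5K1C (1.15). AHNAK2 (-1.68), IFI6 (-1.53), PIMREG (-1.43), AHNAK (-1.38), TMX1 (-1.34), and CD70 (-1.32) fell most, followed by SCD (-1.32), a fatty acid desaturase, SEMA3F (-1.29), PIK3IP1 (-1.21) and SELENOP (-1.20). Of the 6 other NF2 probe sets 1 was at -0.01, and NF2 lost its call when probe sets were averaged (adjusted p = 0.120), as HMGCS1 did (0.290). Of 20 p53 targets 0 rose and 7 fell, or 11 over the list alone, including CDKN1A (-0.66), ZMAT3 (-1.09), FAS (-0.63) and TRIAP1 (-0.47). The list was called lower (adjusted p = 4.30e-09, and 0.0145 with an estimated correlation). Interferon response genes (0 higher and 3 lower, or 0 and 5 over the list alone; ISG15 -1.12, OAS3 -1.11), FOXO targets (2 and 4, or 2 and 5; TRIB1 0.77, BCL2L11 -0.45) and cholesterol synthesis genes (0 and 2, or 0 and 3; IDI1 -0.46, HMGCS1 -0.73) were called lower. Their adjusted p-values were 0.000582, 0.00997 and 0.00997, and the calls were lost at adjusted p = 0.0503, 0.0517 and 0.0517 with an estimated correlation. Mitosis and G2/M genes had 0 higher and 1 lower (CENPA -0.53; list adjusted p = 0.0622). E2F targets had 0 and 3 (UNG -0.37), apoptosis genes 2 and 1 (BID 0.45), immediate early genes 2 and 2 (KLF2 0.94) and stress response genes 3 and 1 (SLC7A11 1.02). Glycolysis and hypoxia genes had 1 and 1, autophagy 2 and 2, PI3K signalling 2 and 2, extracellular matrix 1 and 1 (TNC 0.88), and epithelial markers 1 and 1 (EPCAM 0.79, KRT8 -0.43). The counts were 0 and 0 for histones, estrogen receptor targets, NF-kB genes, ribosomal proteins, and neural and osteoblast markers. Of the lists not called, the counts adjusted over the list alone differed for apoptosis (3 and 3), immediate early (4 and 3), stress response (3 and 2), autophagy (3 and 3), PI3K signalling (3 and 3), extracellular matrix (1 and 4), epithelial (1 and 2) and osteoblast genes (1 and 1). With 2 arrays, this comparison leaned on single samples: CD70, BCL2L11 and HMGCS1 lost their calls without the shFOXO33 array (adjusted p = 0.0504, 0.0856 and 0.108), TRIM58 and OAS3 without the shFOXO707 array (0.0682 and 0.174), and CENPA without either (up to 0.0797). BID lost its call without any 1 of 2 arrays (adjusted p up to 0.137), PIK3IP1 and UNG of 3 (0.149 and 0.156), SELENOP of 4 (0.264) and KRT8 of 5 (0.161). With only the arrays compared, IDI1 (adjusted p = 0.0590), BID (0.0745), BCL2L11 (0.111), CENPA (0.0687), OAS3 (0.0557), SELENOP (0.0654) and UNG (0.109) lost their calls, and BID also when probe sets were averaged (0.0685). Cholesterol synthesis genes lost the list call with only shFOXO33 (adjusted p = 0.133) and without the shFOXO707 array (0.0674). After median centring the counts were 1 and 2 for apoptosis, 1 and 3 for immediate early, 1 and 3 for PI3K signalling, 1 and 2 for extracellular matrix, 2 and 1 for stress response, 0 and 8 for p53 targets and 0 and 1 for osteoblast genes. After quantile normalization they were 2 and 2 for apoptosis, 2 and 3 for immediate early, 2 and 3 for PI3K signalling, 1 and 2 for extracellular matrix and 1 and 0 for ribosomal protein genes.

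The knockdown effects with and without OHT resembled each other but share no array. Across genes they correlated at r = 0.676, and 87.9% of the 1756 genes called with OHT had the same sign without it. In both conditions 407 genes were called in the same direction, against 73.5 for independent lists, and 10 in opposite directions.

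In knockdown cells, OHT raised 1592 genes and lowered 2880. After median centring 2221 were higher and 1736 lower, so that the higher share moved from 35.6% to 56.1%, and after quantile normalization 1777 were higher and 2442 lower (42.1%). The median of all genes was -0.20. HEY1 rose by 5.31 ± 0.08 (SE) log2, and ID4 (4.58), FA2H (4.38), ABCG2 (4.35), MYB (4.28), TM6SF1 (4.28), PLCL2 (3.94), the dopamine receptor gene DRD5 (3.93), KLHL21 (3.85) and CITED1 (3.76) followed. TNFRSF11B (-4.01 ± 0.26, SE), ANKRD1 (-3.77), CCN2 (-3.68), ADAMTS1 (-3.47), ACKR3 (-3.44), SOX9 (-3.37), ARID5B (-3.26), the cytokine gene LIF (-3.24), RIN2 (-3.16) and EDN1 (-3.07) fell most. E2F targets had 22 higher and 12 lower, or 29 and 4 after median centring, with CCNE1 at 3.12, CCNE2 at 2.92 and SLBP at 2.27. The list was called higher (adjusted p = 0.00589, but adjusted p = 0.931 with an estimated correlation, and adjusted p = 0.196 without the shFOXO707 array without OHT). Apoptosis genes had 7 higher and 8 lower (HRK 2.96, MAP3K5 3.28, BCL2L11 0.91, CASP8 -2.10) and p53 targets 3 and 12 (XPC -1.69). FOXO targets had 6 and 13 (KLF6 -2.72, TRIB1 0.96, CDKN1B 1.47) and mitosis and G2/M genes 5 and 18 (PRC1 0.82, NUSAP1 0.71, CENPE -1.14, UBE2C -0.75). Immediate early genes went 6 up and 10 down, stress response genes 4 and 7, interferon response genes 1 and 6, autophagy genes 2 and 8, PI3K signalling genes 8 and 9, cholesterol synthesis genes 3 and 6 and glycolysis and hypoxia genes 6 and 4. After median centring the counts were 8 and 9 for immediate early, 5 and 4 for stress response, 3 and 3 for interferon response, 5 and 6 for autophagy, 8 and 4 for PI3K signalling, 6 and 5 for cholesterol synthesis and 11 and 3 for glycolysis and hypoxia genes. They were 9 and 12 for mitosis and G2/M genes, 4 and 9 for p53 targets, 0 and 0 for histones, 2 and 2 for NF-kB genes and 1 and 0 for each of the epithelial, neural and osteoblast markers. Histones went 0 up and 3 down (0 and 0 over the list alone), extracellular matrix genes 1 and 6 (0 and 3 over the list alone, and 3 and 2 after median centring), estrogen receptor targets 3 and 2 (3 and 3 over the list alone), NF-kB genes 1 and 2, and epithelial, neural and osteoblast markers 0 and 0, 1 and 1, and 1 and 1. Apoptosis genes turned to 11 up and 6 down and FOXO targets to 8 and 8 after median centring, and the lists other than E2F targets had adjusted p between 0.659 and 0.909. Ribosomal protein genes had 0 higher and 1 lower, which turned to 8 higher and 0 lower after median centring and to 0 and 7 after quantile normalization. Quantile normalization gave 1 and 6 for extracellular matrix, 2 and 5 for cholesterol synthesis, 5 and 6 for stress response, 2 and 3 for interferon response, 7 and 4 for PI3K signalling and 2 and 1 for NF-kB genes, 10 and 6 for apoptosis genes and 7 and 12 for FOXO targets. CDC6 differed by 0.29 (adjusted p = 0.151), and FOXO3, which rose by 1.29, lost its call without the shFOXO33 array without OHT (adjusted p = 0.131) and with only the arrays compared (0.0893).

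The responses to OHT in scrambled and knockdown cells, which share no array, correlated across genes at r = 0.964 with a slope of 0.854, and 98.4% of the genes called in scrambled cells had the same sign in knockdown cells. In both, 4236 genes were called in the same direction, against 1720 for independent lists, and 3 in opposite directions. The retained response was taken over the 200 genes with the largest moderated t for a rise in 2 of the scrambled arrays of each treatment. The median response was 2.24 in the scrambled arrays held out and 2.05 in knockdown cells. The ratio was 0.918 on average, from 0.893 to 0.946 over the 36 choices of arrays, and it was 0.939 with shFOXO33 alone and 0.925 with shFOXO707 alone.

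**Figure D3:**
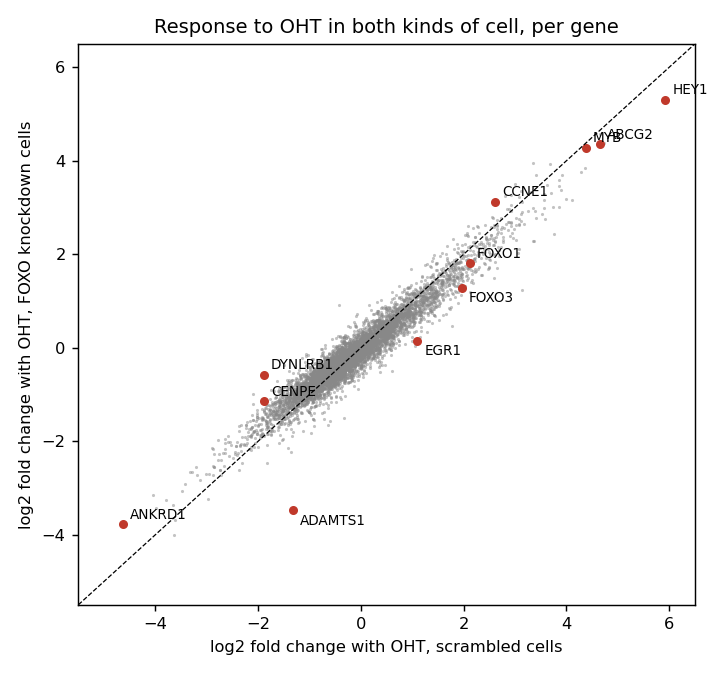
Log2 fold change with OHT of 7720 genes (dots) in scrambled cells (x axis) and in FOXO knockdown cells (y axis), with named genes in red and equality as a dashed line. Genes lie along a line with a slope of 0.854 (r = 0.964), while ADAMTS1 (-1.33 and -3.47) and EGR1 (1.09 and 0.15) lie below equality and CENPE (-1.89 and -1.14) above.

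With the hairpins pooled, 6 genes had a more positive and 21 a more negative response to OHT in knockdown cells. With 6 groups, where the difference between the hairpins does not enter the error, the counts were 383 and 365. With only shFOXO33 they were 255 and 289, and with only shFOXO707 220 and 224. In simulation 23.0% of differences of 0.5 log2 were recovered. The fall of DYNLRB1 was smaller in knockdown cells (-0.57 against -1.89, a difference of 1.32 ± 0.16, SE; adjusted p = 0.00398). The falls of CENPE (0.75), of NCAPH (0.73), a subunit of condensin, and of the receptor NOTCH2 (0.69) were also smaller. The mitotic kinesin KIF18B had a signal of 1317 in scrambled cells and 2239 in knockdown cells with OHT (0.77). ADAMTS1 fell further in knockdown cells (-2.15 ± 0.24, SE, adjusted p = 0.00234). It started higher there without OHT, whereas scrambled cells without OHT had dim signals of 111 to 129 that could fall little further. The difference for ADAMTS1 therefore does not show a stronger repression by OHT. HABP4 (-1.30), the growth factor FGF9 (-0.94), the immediate early transcription factor EGR1 (-0.94) and TRIB1 (-0.93, adjusted p = 0.000665) rose less. TRIB1 was already higher by 0.77 log2 with knockdown without OHT, so its difference includes a higher start. An unadjusted p under 0.05 was reached by 813 genes. Of 34 mitosis and G2/M genes 1 was called, or 19 when adjusted over the list alone, all toward a more positive response, and the list was called (adjusted p = 1.83e-18, and 0.0306 with an estimated correlation). The median of the list relative to scrambled cells without OHT was -0.76 to -0.59 on scrambled arrays with OHT, -0.41 to -0.38 on knockdown arrays with OHT, and -0.02 for shFOXO33 and -0.13 for shFOXO707 without OHT. Immediate early genes were called toward a more negative response (0 and 2, or 0 and 5 over the list alone, with EGR1 and ATF3 at -0.77; adjusted p = 6.05e-06, and 0.0284 with an estimated correlation). With only shFOXO33 this call was lost (adjusted p = 0.0876), and the median of the list relative to that of all genes moved from -0.23 to -0.10. Cholesterol synthesis genes had 0 members called, or 1 over the list alone (DHCR7 0.48, adjusted p = 0.118). That list was called toward a more positive response (adjusted p = 0.00797, and 0.0432 with an estimated correlation), but not with only shFOXO33 (adjusted p = 0.0876) or without the shFOXO707 array without OHT (0.0755). Ribosomal protein genes were called with 0 members (adjusted p = 0.0146, but adjusted p = 0.634 with an estimated correlation). Their median relative to that of all genes, 0.07 log2, turned to -0.03 after quantile normalization and to -0.02 without the shFOXO707 array without OHT. The call was also lost without a trend in the variance prior (adjusted p = 0.0730), with only shFOXO33 (0.0876), and without replicate 4 of scrambled cells without OHT (adjusted p = 0.0621), replicate 2 of scrambled cells with OHT (0.0699) and replicates 1 (0.227) and 2 (0.0753) of shFOXO33 with OHT. The other 16 lists had adjusted p between 0.0682 and 0.997, with 1 FOXO target (TRIB1), 1 stress response gene (ATF3) and 1 glycolysis and hypoxia gene (VEGFA, -0.58) called, all toward a more negative response. Adjusted over the list alone, 3 p53 targets had a more positive response, and 2 glycolysis and hypoxia genes, 1 estrogen receptor target and 1 osteoblast marker a more negative one. The BH3-only gene BCL2L11 differed by 0.07 (adjusted p = 0.953) and CDKN1B by 0.01, and neither was called.

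These interaction counts rested on single arrays. The more positive and more negative responses numbered 1 and 6, 1 and 5, and 3 and 9 without replicates 1, 3 and 4 of scrambled cells without OHT. They numbered 1 and 3, 5 and 8, 3 and 7, and 2 and 5 without replicates 1 to 4 of scrambled cells with OHT. Without the shFOXO33 array without OHT they rose to 31 and 50, and without the shFOXO707 array without OHT they were 23 and 18. Without replicate 2 of shFOXO33 with OHT they were 3 and 6, without replicate 1 of shFOXO707 with OHT 5 and 8, and without its replicate 2 they were 15 and 26. DYNLRB1, ADAMTS1 and TRIB1 were called without each of the 14 arrays, FGF9 lost its call without replicate 1 of scrambled cells with OHT (adjusted p = 0.0612), and HABP4 without that array or the shFOXO707 array without OHT (up to 0.0612). NOTCH2 lost its call without any 1 of 6 arrays (up to 0.0617), KIF18B of 8 (0.0617), CENPE of 10 (0.0855), EGR1 of 10 (0.0986), VEGFA of 10 (0.0855), ATF3 of 12 (0.121) and NCAPH of 13 (0.106). VEGFA also lost it when probe sets were averaged (0.171). Without a trend in the variance prior EGR1 (0.0506), ATF3 (0.0506) and NCAPH (0.0520) lost it, and without a filter ATF3 (0.0715) and NCAPH (0.0654). NCAPH lost it after median centring (0.0540) and quantile normalization (0.0620) as well.

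**Figure D4:**
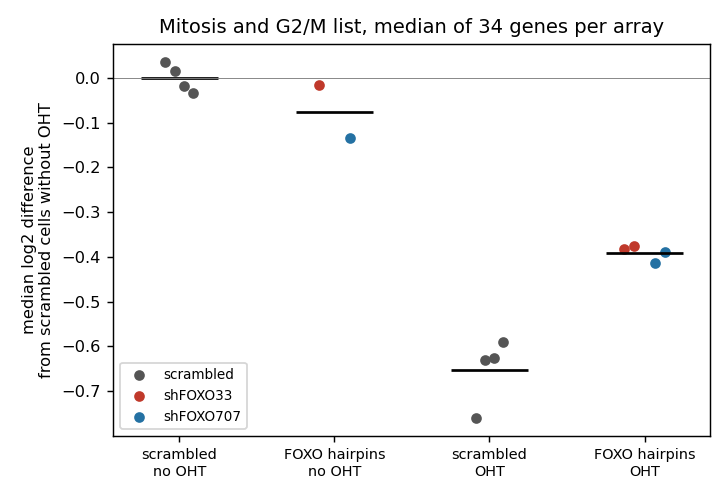
Median log2 difference of 34 mitosis and G2/M genes from the mean of scrambled cells without OHT, 1 dot per array coloured by virus, with lines at the group means. Scrambled arrays with OHT lie between -0.76 and -0.59 and knockdown arrays with OHT between -0.41 and -0.38.

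Genes that rose with OHT and fell with knockdown in the presence of OHT were counted as an overlap. A lower signal with knockdown does not show that the response to OHT depends on FOXO. ISG15, for example, was also lower with knockdown without OHT. The overlap held 290 genes, which is 15.6% of the genes that rose with OHT. By size of the knockdown effect they were led by FOXO3, CEMIP, ISG15, EGR4 and FOXO1. FOXO3 and FOXO1 are the targets of the hairpins, so their fall was set by the design. In limma's interaction neither was called (-0.67 and -0.30, adjusted p = 0.820 and 0.855 in the fit of all probe sets). Independent lists of the same sizes would share 148. Both comparisons used the same scrambled arrays with OHT, which favours such opposite calls. With those arrays split between the comparisons, 120 genes (108 to 136 over the splits) were shared, against 64.1 for independent lists. The overlap was 407 after median centring, 726 with 6 groups and 7 when both changes had to be at least 2-fold. Without replicate 1 of scrambled cells with OHT it fell to 186. Genes that fell with OHT and rose with knockdown numbered 835 (528 for independent lists; 465 against 256 with split arrays). The combinations in the same direction were 125 genes higher in both (273 for independent lists) and 184 lower in both (287).

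The hairpins gave large differences from each other in addition to shared effects. With OHT, limma called 1706 genes higher and 1655 lower with shFOXO707 than with shFOXO33, 237 and 154 of them at least 2-fold. The matrix protein gene SPARC (3.29 ± 0.06, SE), with a signal of 804 with shFOXO33 and 8034 with shFOXO707, IGFBP5 (3.12), the ubiquitin ligase subunit RBX1 (2.90), IARS2 (2.75) and DSE (2.58) were higher with shFOXO707. Caveolin-1 gene CAV1 (-3.96 ± 0.08, SE), with a signal of 3314 with shFOXO33, 199 with shFOXO707 and 2603 in scrambled cells, the receptor kinase AXL (-3.20), PCLO (-3.09), R3HDM1 (-2.92) and MAP4 (-2.80) were lower. These differences were also present without OHT, where the hairpin differences correlated with those with OHT at r = 0.801 across genes and 94.1% of the 3361 called genes had the same sign.

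Against scrambled cells with OHT, 2149 genes were higher and 1663 lower with shFOXO33, and 1897 and 1327 with shFOXO707. Of these, 880 were higher with both (528 for independent lists) and 509 lower with both (286), while 229 and 316 went in opposite directions. Both effects use the same scrambled arrays. With these arrays split, 669 genes were higher with both (374 for independent lists) and 386 lower with both (214). The effects correlated across genes at r = 0.297, and at 0.259 (0.253 to 0.263) with split arrays. Simulated unchanged groups gave 0.334, which follows from the number of shared arrays alone. It is therefore no benchmark for how well the hairpins agree. The covariance of the effects was 0.0496 against a simulated 0.00512, a difference of 0.0445.

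**Figure D5:**
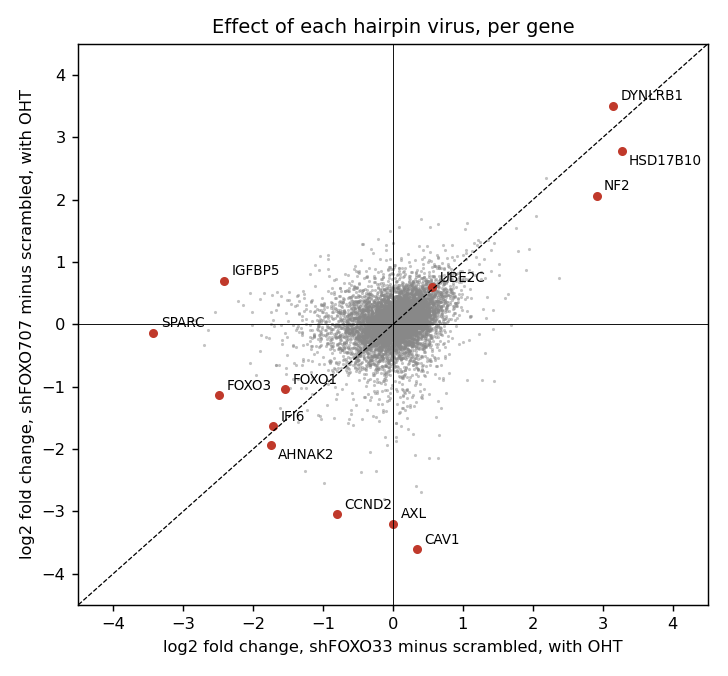
Log2 fold change against scrambled cells with OHT of 7720 genes (dots) for shFOXO33 (x axis) and shFOXO707 (y axis), with named genes in red and equality as a dashed line. DYNLRB1 (3.15 and 3.51) rose with both hairpins and IFI6 (-1.71 and -1.64) fell with both, while SPARC (-3.43 and -0.13) fell with shFOXO33 and CAV1 (0.35 and -3.61) with shFOXO707.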

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

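Of the tests in this part, the spiked controls in scrambled and knockdown cells apart, the comparison of hairpin differences with and without OHT, the count of genes in which 1 virus stands apart and the comparison of the hairpins over shared higher genes were chosen only after the results were seen.

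With OHT more genes were lower than higher in scrambled cells, 3585 against 1854. If scaling of each array to a common trimmed mean were the cause, hybridization controls spiked in at fixed amounts would be lower on arrays with OHT by about the shift of the median gene. The 18 spiked probe sets differed by 0.0309 ± 0.0459 (SE) log2 over all arrays, above the midpoint between no shift and the median shift, -0.114, by more than 2 SE. That midpoint comes from scrambled cells, in which the controls differed by -0.0339 ± 0.0568 (SE), only 1.41 SE above it, against 0.0920 ± 0.0517 (SE) in knockdown cells, so scaling and a change in RNA per cell, which was not measured, cannot be told apart with 4 arrays per group. Of the 35 splits of the 8 scrambled arrays, 1 gave as many lower genes and 1 as many higher genes. It was the real one in each case, the smallest share that 35 splits can give, and the highest of the others was 0. The other splits mix arrays with and without OHT, which puts the response into the error and favours counts of 0. The result holds for the division of these arrays. Whether it holds between cultures cannot be told, since the origin of the replicates is not given in the sources used here.

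With OHT the hairpins differed in 3361 genes. If the higher ACTB 3'/5' ratio of the shFOXO707 arrays with OHT, a candidate source of bias, were the cause, the differences would shrink without OHT, where the log ratio of ACTB between hairpins was 0.448 of that with OHT. The slope of the differences without OHT on those with OHT was 0.807, and 0.775 to 0.792 over single pairs of arrays. This argues against it as the only cause, mainly for genes with large differences, which weigh most in the slope. A part played by this bias stays open, also because each hairpin had 1 array without OHT. A deeper FOXO knockdown with shFOXO33 would leave few genes further from scrambled cells with shFOXO707. Yet 44.8% of the 391 genes that differed by at least 1 log2 (175 genes) lay further with shFOXO707. In 317 the effects of the hairpins had opposite signs, whatever their size. That number includes genes that 1 hairpin hardly changed, such as CAV1. It also stays open that each hairpin may act on transcripts other than its targets, which was not tested because each virus is 1 sequence.

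With OHT 40 genes were at least 2-fold higher with knockdown, led by DYNLRB1 and HSD17B10. If the scrambled virus lowered such transcripts, genes in which scrambled cells stand apart would mostly be lower there, and with OHT 62.5% of 32 were (exact 95% interval 43.7% to 78.9%), against 89.7% of 107 for shFOXO33 and 81.5% of 81 for shFOXO707, while without OHT the shares were 73.7%, 96.5% and 75.3%. With OHT 20 of the 20 lower genes belong to the 40, so the share restates the pattern and decides nothing. If loss of FOXO1 and FOXO3 raised them, shFOXO33, which left less FOXO3, would raise them more, and the median of shFOXO33 minus shFOXO707 was 0.0607 (quartiles -0.144 and 0.548), with 21 of 40 higher with shFOXO33. Both explanations may hold and cannot be told apart here, because all scrambled arrays carry 1 sequence.

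Chance was also examined for other results by splitting the 8 arrays with OHT, scrambled and knockdown, in 35 ways. For knockdown with OHT 1 split gave as many higher genes (real value 1138, highest other 1) and 1 as many lower genes (618, highest other 0). Each was the real split, the smallest share that 35 splits can give, with the same limits. The other splits put differences between the viruses into the error. The splits therefore cannot separate loss of FOXO1 and FOXO3 from other differences between the viruses. The overlap with the genes that rose with OHT (real value 290, highest other 0, 1 of 35 splits) was not tested by the splits. The other splits called too few genes to overlap. For the number of gene lists called the splits did not exclude chance. With knockdown 2 of 35 gave as many (real value 6, highest other 6). With OHT in scrambled cells 15 of 35 did (real value 1, highest other 3). The other knockdown split with 6 lists exchanged only 1 array of each side. Such splits keep part of the real difference and can call lists for that reason, so with knockdown they decide nothing about chance.

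The response to OHT differed between scrambled and knockdown cells in limma's interaction for several genes named above. ATF3 (-0.77), HEY1 (-0.62) and VEGFA (-0.58) were among those called. The largest differences each way, 10 in all, are given next. The difference was 1.32 for DYNLRB1, 0.77 for KIF18B, 0.75 for CENPE, 0.73 for NCAPH and 0.69 for NOTCH2, and -2.15 for ADAMTS1, -1.30 for HABP4, -0.94 for FGF9, -0.94 for EGR1 and -0.93 for TRIB1.

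Single arrays stood apart from the others of their group of 4 in 33 of 498 checks. The checks covered named genes, the median signal and the ACTB and GAPDH 3'/5' ratios. An array was flagged when the gap to the nearest array divided by the range passed Dixon's limit, and chance gives about 1 in 20 groups. The ratio does not give the size of the gap. MSH6 was flagged at a signal of 5388 against 5481 to 5497, and SLC2A1 at 97.9 against 156 to 169. In scrambled cells without OHT the ratio was 0.868 for ACKR3, 0.869 for KLF10, 0.990 for HMGA2, 0.903 for NR4A1, 0.913 for ADAMTS1 and 0.879 for CPOX, all set by replicate 4. It was 0.957 for CASP8, 0.905 for KLF6, 0.835 for USP18, 0.864 for AKT1, 0.903 for SCD and 0.842 for RBX1, set by replicate 1. It was 0.954 for FAS and 0.836 for IFI6, set by replicate 3, and 0.885 for RPL18 and 0.958 for VEGFA, set by replicate 2. In scrambled cells with OHT it was 0.899 for ARID5B, 0.842 for KDM3A, 0.842 for SLC2A1 and 0.920 for NCAPH (replicate 1), 0.911 for TRIM22 and 0.949 for AXL (replicate 2), and 0.919 for GABBR2 and 0.914 for EDN1 (replicate 3). Replicate 4 set it for BCL2L11 (0.907), PREPL (0.852) and PHLDA3 (0.847). In knockdown cells with OHT shFOXO707 replicate 2 set it for CEMIP (0.894), TFEB (0.857) and PTCH1 (0.849), shFOXO707 replicate 1 for CENPA (0.848) and NR4A1 (0.868), and shFOXO33 replicate 2 for MSH6 (0.861).

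Outside the named genes, 373 of 3151 probe sets that name no gene or several were higher with OHT than without in scrambled cells, and 734 were lower.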

How the results depend on the processing

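Of these alternatives, the fit of arrays numbered 1 and 2 without a block was chosen only after the data were seen. Named genes were compared with each alternative, leaving aside single arrays left out. They kept direction and side of the threshold in 4549 comparisons, lost the call in 267 and gained it in 135. They moved in 43 and reversed in 5. For lists these counts were 1375, 18, 22, 83 and 2. With the minimum change of 1 log2, a called gene below that size lost its call by definition, and the 267 include such losses. With single arrays left out the counts were 4824, 213, 26, 47 and 0 for genes and 1328, 10, 19, 41 and 2 for lists. The cause of the changes was not tested except where the setting itself shows it. With log2(signal + 64), the 60th percentile filter, quantile normalization and the mean of probe sets, 12, 20, 11 and 11 genes had a more positive interaction. Median centring gave 2366 genes lower with OHT in scrambled and 1736 in knockdown cells. With 6 groups, which take the hairpin difference out of the error, knockdown gave 2039 higher and 1601 lower with OHT and 1187 and 1179 without, the interaction 383 and 365, and the overlap 726. With only the arrays compared, knockdown without OHT gave 151 and 135. At 2-fold or more the counts were 781 and 976 (OHT, scrambled), 641 and 733 (OHT, knockdown), 40 and 38 (knockdown with OHT), 29 and 21 (without), 1 and 2 (interaction), 237 and 154 (hairpins), and 7 in the overlap. With only shFOXO33 knockdown gave 2151 and 1670 with OHT, 1124 and 1136 without, and 255 and 289 in the interaction; with only shFOXO707 1875 and 1321, 1103 and 980, and 220 and 224. The hairpin correlation was 0.278 at the 60th percentile filter and 0.311 without a filter, and the retained response 0.868 with 500 genes.

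Reversed values were COL6A1 (0.0142) and RPL10A (0.0391) with OHT in knockdown cells after median centring, KRT18 (0.36) with knockdown and OHT with only shFOXO33, and CCNE1 (0.25) and CDC6 (-0.30) with only shFOXO707. The test of the ribosomal protein list changed direction in the interaction after quantile normalization (median relative to that of all genes -0.0263), in knockdown without OHT with only shFOXO33 (0.0602), and in both without the shFOXO707 array without OHT. Over arrays left out that median ranged from -0.0166 (without the shFOXO707 array without OHT) to 0.153 (without the shFOXO33 array without OHT) in the interaction, and from -0.108 (without the shFOXO33 array) to 0.0602 (without the shFOXO707 array) in knockdown without OHT.

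A block for the replicate number gave 13 higher and 6 lower genes with knockdown and OHT and an overlap of 2, against 92 and 48 for the same arrays without the block. Deviations of scrambled arrays of the same number correlated at 0.0265, 0.0462, 0.0241 and -0.0146, and for numbers 1 and 4 another number correlated more (0.0406 and 0.0245), so the numbers were not taken to pair the samples.

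Leaving out each array in turn gave 1760 to 1913 higher and 3357 to 3662 lower (OHT, scrambled), 1463 to 1582 and 2496 to 2909 (OHT, knockdown), 866 to 1269 and 429 to 762 (knockdown with OHT) and 252 to 389 and 160 to 287 (without). The interaction ranged from 1 (without scrambled replicate 1 without OHT) to 31 more positive and from 3 (without scrambled replicate 1 with OHT) to 50 more negative, both highest without the shFOXO33 array without OHT, the hairpin difference from 1393 to 1727 and 1283 to 1688, the overlap from 186 (without scrambled replicate 1 with OHT) to 366, the hairpin correlation from 0.277 to 0.311 and the retained response from 0.907 to 0.947. A group left with 1 array was assumed to vary like the others. No detection calls were used here, so the filter alone bounds how dim a gene could be.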

Other observations

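The genes in this part were chosen only after their values were seen, while the comparisons were those planned for every gene. HEY1, which rose most with OHT in scrambled cells, was already higher in knockdown cells without OHT, with a signal of 254 ± 8.98 (SD, n = 2) against 157 ± 16.6 (SD, n = 4) in scrambled cells, a difference of 0.65 ± 0.08 log2 (SE; limma adjusted p = 0.000563). With OHT the signals were 10722 ± 512 (SD, n = 4) and 10472 ± 276 (SD, n = 4), a difference of 0.03 log2 (adjusted p = 0.764), and the interaction was -0.62 (adjusted p = 0.0296). PTCH1, a receptor of Hedgehog ligands, rose by 1.59 in scrambled and by 0.71 in knockdown cells with OHT (interaction -0.88). The cell cycle inhibitor CDKN1C rose by 2.17 and 1.46 (-0.71), and PRDM2 by 1.91 and 1.25 (-0.66; adjusted p = 0.00814), while VEZF1, a zinc finger transcription factor, fell by 1.45 and by 0.83 (0.62). HEY1 lost the interaction call without any 1 of 9 arrays (adjusted p up to 0.0855), which were the 4 scrambled arrays with OHT, scrambled replicates 1 and 3 and the shFOXO707 array without OHT, and shFOXO33 replicate 2 and shFOXO707 replicate 1 with OHT. PTCH1 lost it without these and scrambled replicate 4 without OHT (10 arrays, up to 0.0855), and CDKN1C also without scrambled replicate 2 (11 arrays, up to 0.0911). VEZF1 lost it without scrambled replicate 1 or 3 without OHT, or 1 or 4 with OHT (up to 0.0612). PRDM2 kept it with each array left out, but lost it when its probe sets were averaged (-0.29; adjusted p = 0.391), as did CDKN1C (-0.46; 0.136), and HEY1 lost it without a trend in the variance prior (0.0506).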
